A study of Mus musculus with 6 samples.

How the data were processed

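RNA from whole skin of 6 C57BL/6 mouse samples (3 untreated, 3 treated with SspA and HDM) was made into libraries with a stranded mRNA kit, per the labels' protocols. Per the submitters' processing notes, bcl2fastq 2.20.0.422, STAR and DESeq2 were used with genome build mm10. The read counter and the filters are not given in the sources used here. The labels do not say that the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

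The authors deposited 1 table of 17564 genes. Its 6 value columns are a scaled signal per gene, per the file headers and the values, and each sums to between 6339993 and 6340285. The table also holds the authors' deposited log2 fold changes and the authors' deposited p-values and adjusted p-values, and transcript lengths. The test planned was for raw counts. Since the deposited values are scaled signal, limma on log2(value + 1) was used instead, as the plan foresaw. Fold changes are on that scale, which understates the change of low genes.

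In each column the values were whole multiples of 1 step, the value of 1 read, and 100.0% of values lay within 0.1 of a whole number of reads. Recovered reads per library were 5770072, 4928245 and 5580401 in untreated replicates 1 to 3 and 5606959, 5821622 and 7545567 in treated replicates 1 to 3. A floor of 3 reads over a group was 1.17 scaled reads in the untreated and 1 in the treated group. Floors and 95% intervals cover counting error only. Reads per base of transcript never exceeded 0.923, a limit that no source used here states, and whether reads at 1 position were counted once is not given. Scaled values of genes with many reads per base were lower in the deepest library, which is treated, than in the shallowest, which is untreated, so depth and treatment are not separated there. 3003 genes averaged over 0.2 reads per base.

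Genes passing the edgeR 4.0.16 function filterByExpr (minimum count 10, minimum total 15) on recovered reads were tested with limma 3.58.1 in R 4.3.3, with a trend in the spread, group as the only term, and Benjamini-Hochberg adjustment. A gene was called at adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists, beside an estimated correlation and fry. Before the data were examined, 37 lists with 641 entries were fixed, of which 593 had a row and 543 were tested. Lists with fewer than 3 tested members and the sex-linked list got no test. Those other than the sex-linked list without a test were the B and plasma cell markers and the mitochondrially encoded genes.

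The genes named follow a rule fixed at the same time: 24 core genes whatever their result, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap of the groups (leaving out predicted genes and antigen receptor segments), and up to 4 members per list with the smallest p. Where a list had 5 or fewer called members in a direction, they were named, and those outside the rule, such as Orm1, were chosen after their values were seen. Follow-up genes in the closing section also fall outside the rule. Flg was not analysed here. Some genes that the rule takes are not reported here.

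The alternatives were DESeq2 1.42.0 and limma-voom on recovered reads, RLE and upper quartile scaling, other filters, stricter thresholds, the replicate number as a block, leaving out hair and muscle genes, leaving out each library, and the authors' deposited comparison. Further alternatives were chosen after seeing the data: the edgeR quasi-likelihood test with TMM on recovered reads, which called 1249 higher and 1204 lower genes, TMM scaling with limma, pseudocounts of 0.5 and 5, reads estimated from filled positions, removal of the loess trend of each library with reads per base, the 4 libraries of like depth, removal of genes over 0.2 reads per base, and limma without a trend in the spread.

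On simulated data drawn from the means, library sizes and dispersions of the 6 libraries, with 200 of 15534 genes changed, the limma test recovered 92% of genes changed 3-fold and 32% of genes changed 1.5-fold, and called 7 of 15334 unchanged genes. The simulation treats genes as independent. Changed genes were drawn only from genes above a minimum of total reads, so recovery of genes with few reads was not measured. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.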

Results

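Whole back skin of 8-week-old C57BL/6 mice was profiled by bulk RNA sequencing in 2 groups of 3 samples. One group was shaved and depilated only. The other also received SspA, the V8 protease of Staphylococcus aureus, at 3 µg together with house dust mite extract (HDM) at 10 µg on the skin surface, repeated after 3 days, and was collected 7 days after the first application. The labels give no collection day for the untreated samples. The deposited table held 17564 genes, and the reads behind its values ranged from 4928245 in untreated replicate 2 to 7545567 in treated replicate 3. Untreated replicates 1 and 3 had 5770072 and 5580401 reads, and treated replicates 1 and 2 had 5606959 and 5821622. Below, U1 to U3 and T1 to T3 stand for untreated and treated replicates 1 to 3. The comparison asked how gene expression in skin differs after exposure to the protease and the mite extract.

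Treated skin carried higher levels of genes of inflammation and of small proline-rich genes of the epidermis. Neutrophil genes had a median log2 fold change of 3.29, the secreted antimicrobial and acute-phase genes 1.44, and the small proline-rich and stress keratin list 1.34. All called members of that last list but Krt6b were Sprr2 genes, which share reads. The stress keratin genes Krt6a and Krt16 did not pass over the 6 libraries. The cytokine genes Il19, Il24 and Il17f, matrix proteases and cell cycle genes were higher as well. The hair shaft and inner root sheath list (median 2.88, with most hair shaft keratin genes below the filter) and melanocyte genes (median 2.12) were also higher. Sebaceous gland, adipocyte, skeletal muscle and cholesterol synthesis genes were lower. Skeletal muscle and adipocyte medians were -0.36 and -0.35 over the 6 libraries but -0.18 and -0.23 in the 4 libraries of like depth. Unequal depth stays open as a part of the fall of muscle and adipocyte genes. The type 2 cytokine genes Il4 and Il13, which are linked to allergic inflammation, had 6 to 21 reads per group. The lists named here passed camera at a preset correlation, while the smallest adjusted p of any list was adjusted p = 0.362 with an estimated correlation.

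Of 15534 genes tested, 1439 were higher and 1123 lower in treated skin (limma, adjusted p under 0.05), and 552 of the higher and 305 of the lower genes changed at least 2-fold. The values of the groups did not overlap for 37.3% of the tested genes, where chance gives 10% for 3 samples against 3. The first principal component held 66.6% of the variance and separated the groups. The authors' deposited table calls 1275 genes higher and 1328 lower, of which 1131 and 1075 were called in the same direction here. Leaving out single libraries lowered the counts by more than 1.5 times in 4 cases, to 675 higher and 543 lower without untreated replicate 1, 751 and 644 without untreated replicate 2, 856 and 623 without treated replicate 1, and 597 and 518 without treated replicate 2. A threshold of adjusted p under 0.01 left 362 and 288, and a test against a 1.5-fold change left 137 and 57.

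**Figure D1:**
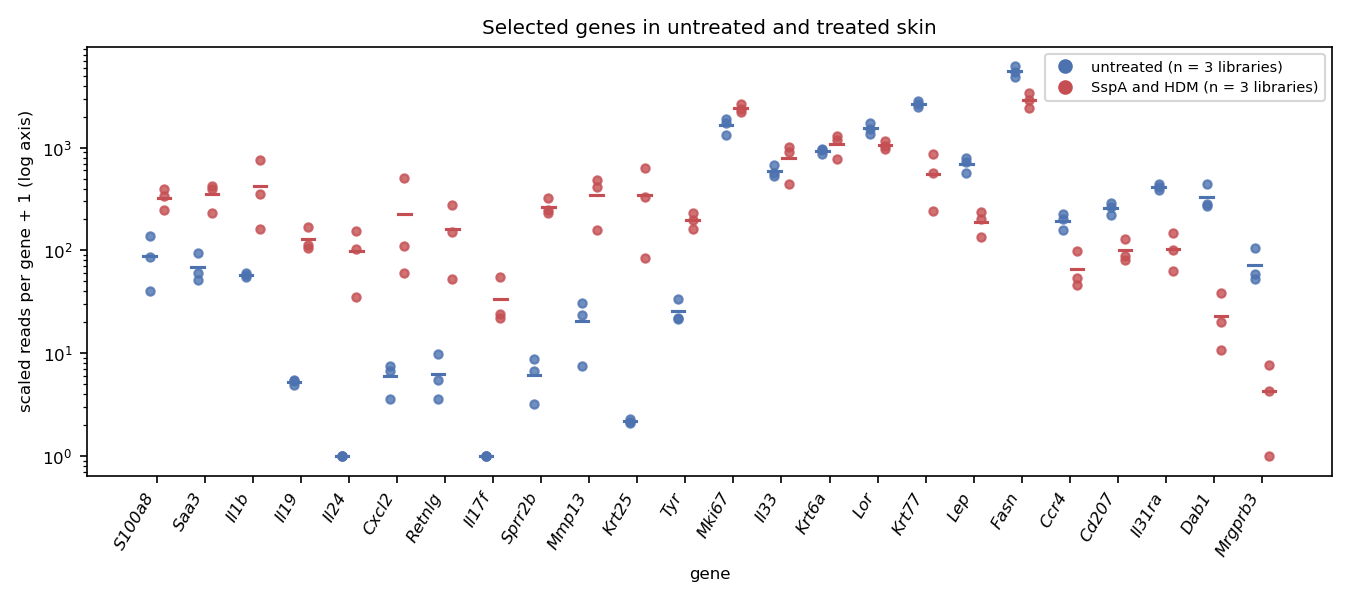
Scaled reads per gene plus 1 (log axis) of 24 genes in each library, with 3 untreated libraries in blue and 3 treated libraries in red and bars at the group means. Il24 and Il17f had no read in any untreated library, while Il33 and Krt6a overlapped between the groups.

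Among the 8 largest rises by the naming rule, Krt25 (log2 fold change 6.90 ± 0.62 SE, adjusted p = 8.76e-04), a keratin of the inner root sheath (mm10 chromosome 11, 99315516 to 99322951), went from 1.18 ± 0.1 to 347 ± 272 scaled reads (SD, n = 3). The untreated value is about that of 1 read per library (1.10, 1.29 and 1.14 scaled reads in U1, U2 and U3). It lies at the floor, so the size of the Krt25 fold change is uncertain. Il24 (chromosome 1, 130882074 to 130887411) and Serpinb3d (chromosome 1, 107078193 to 107083480) had no read in the untreated group, and their treated reads were at least 77.8-fold and 66.6-fold higher than a floor of 3 reads over the group. Reads of Serpinb3d are uncertain, since it has near-identical paralogs. The others were Acod1 (5.81, adjusted p = 0.0057), which makes the antimicrobial metabolite itaconate, Tmprss11b (5.70, adjusted p = 4.91e-04), Cxcl5 (5.66, adjusted p = 0.0109), a neutrophil chemoattractant, Reg1 (5.65, adjusted p = 0.0019) and Trem1 (5.55, adjusted p = 0.0069). The 8 largest falls were Mrgprb3 (log2 fold change -4.44 ± 0.68 SE, adjusted p = 0.0056) at chromosome 7, 48642863 to 48643801, Hamp2 (-4.39, adjusted p = 0.0072), Adh6a (-4.20, adjusted p = 0.0051), Dab1 (-3.99, adjusted p = 0.0013), Skint5 (-3.87, adjusted p = 0.012), a gene of the keratinocyte family that shapes epidermal T cells, Serpinb6e (-3.39, adjusted p = 0.019, 0.069 without U1, 0.0517 without U3, 0.0574 without T1 and 0.0652 without T2), Mucl1 (-3.18, adjusted p = 0.0016) and Pdzrn4 (-3.16, adjusted p = 0.0064). Acod1, Cxcl5 and Trem1 were not called with limma-voom (adjusted p over the alternatives 6.13e-05 to 0.0714, 0.0017 to 0.0976 and 8.68e-05 to 0.0828). Serpinb6e was not called without a trend in the spread (adjusted p over the alternatives 5.77e-05 to 0.069).

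Among epithelial cytokines and growth factors, 10 of 18 tested members rose (11 higher adjusted over the list alone). Epithelial cytokines and growth factors as a list had adjusted p = 1.50e-05 by camera and adjusted p = 0.362 with an estimated correlation. Counts of epithelial cytokines and growth factors were 6 higher without U1 and 1 lower without T3. Il19 went from 4.27 ± 0.359 to 129 ± 34.7 scaled reads (4.59 ± 0.28 SE, adjusted p = 3.91e-04), and Areg (1.67, adjusted p = 0.0017), a ligand of the epidermal growth factor receptor, and Il1b (2.61, adjusted p = 0.0079) also rose. The alarmin genes Tslp (0.41, adjusted p = 0.273) and Il33 (0.34, adjusted p = 0.44, 0.005 without T3) did not pass the test over the 6 libraries. Il6 (1.78, adjusted p = 0.0326, 0.0521 without U1, 0.0979 without U2, 0.0715 without U3, 0.11 without T1 and 0.108 without T2) rose over the 6 libraries. Il1b was not called with limma-voom (adjusted p over the alternatives 1.17e-04 to 0.0587). Il33 was called in the 4 libraries of like depth (adjusted p over the alternatives 0.0048 to 0.824). Il6 was not called with limma-voom or the trend with reads per base removed or without a trend in the spread (adjusted p over the alternatives 0.0081 to 0.11).

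Of the antimicrobial and acute-phase genes, 14 of 23 tested members rose and 1 fell, namely Orm1 (15 higher and 1 lower adjusted over the list alone). Antimicrobial and acute-phase genes as a list had adjusted p = 3.49e-06 by camera and adjusted p = 0.362 with an estimated correlation. Saa3 (log2 fold change 2.35 ± 0.28 SE, adjusted p = 0.0025) rose from 67.5 ± 22.8 to 349 ± 105 scaled reads, and the calgranulin genes S100a8 (2.03, adjusted p = 0.0114) and S100a9 (1.99, adjusted p = 0.0064) and Slpi (1.87, adjusted p = 0.005), a protease inhibitor of mucosal surfaces, rose with it. The counts of Defb4 and Saa3 are uncertain where reads are shared with other members of their families.

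Among chemokine genes, 4 of 17 tested members rose, namely Ccl3, Ccl4, Cxcl1 and Cxcl2, and 2 fell, namely Cxcl12 and Cxcl14 (7 higher and 2 lower adjusted over the list alone). Chemokines as a list had adjusted p = 0.0362 by camera (0.0527 without U2, 0.0618 without U3 and 0.137 without T2) and adjusted p = 0.386 with an estimated correlation. Counts of chemokines were 8 higher without T3 and 1 lower without U1, U2, U3, T1 or T3. The list was not called without a trend in the spread (adjusted p 0.0032 to 0.137 over the alternatives other than the estimated correlation). Cxcl2 (4.72, adjusted p = 0.0047) and Ccl4 (5.04, adjusted p = 0.0043) rose, and Cxcl14 (-0.74, adjusted p = 0.008), which is expressed in resting epidermis, fell. Cxcl1 (1.49, adjusted p = 0.0131, 0.0502 without T2) rose over the 6 libraries, whereas the eosinophil chemoattractant Ccl11 (0.15, adjusted p = 0.515) did not pass. Ccl3 and Cxcl2 were not called with limma-voom (adjusted p over the alternatives 3.05e-05 to 0.0566 and 6.64e-06 to 0.0839). Cxcl12 was not called in the 4 libraries of like depth or without a trend in the spread, U1, U2, U3, T1 or T3 (adjusted p over the alternatives 0.0121 to 0.109).

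For type 17 genes, 3 of 9 tested members rose, namely Il17f, Il23r and Cxcl5, and 1 fell, namely Ccl20 (4 higher and 1 lower adjusted over the list alone). Type 17 genes did not pass as a list, with adjusted p = 0.0983 by camera, 0.045 without U1. Counts of type 17 genes were none lower without U1, U2, U3, T1 or T2. The list was called with at least 1 CPM in 3 libraries or edgeR (adjusted p 0.021 to 0.209 over the alternatives other than the estimated correlation). Il17f had no read in the untreated group and was at least 26.9-fold higher than the floor in the treated group (adjusted p = 0.0011). Il17a, below the filter, had 2 reads in the untreated and 36 in the treated group, a ratio of 15.4 (95% counting interval 3.98 to 132). Il23r was not called with DESeq2 or the trend with reads per base removed, in the 4 libraries of like depth or without a trend in the spread, U2, U3, T1, T2 or T3 (adjusted p over the alternatives 0.0337 to 0.128). Ccl20 was not called with limma-voom or edgeR or without a trend in the spread, U1, U2, U3, T1 or T2 (adjusted p over the alternatives 0.0047 to 0.125).

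In the type 1 and interferon response list, 10 of 23 tested members rose (13 higher adjusted over the list alone). Type 1 and interferon response genes as a list had adjusted p = 4.22e-07 by camera and adjusted p = 0.362 with an estimated correlation. Counts of type 1 and interferon response genes were 4 higher without U1 or T2. The interferon-induced genes Rsad2 (0.97, adjusted p = 0.0086), Ifit1 (1.08, adjusted p = 0.0086) and Oasl1 (1.41, adjusted p = 0.0107) rose. Ifng had 1 read in the untreated and 11 in the treated group, a ratio of 9.44 (95% counting interval 1.37 to 406), and was below the filter.

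For type 2 cytokines and receptors, 1 of 9 tested members rose, namely Il1rl1, and 2 fell, namely Gata3 and Ccr4 (2 higher and 2 lower adjusted over the list alone). Type 2 cytokines and receptors did not pass as a list, with adjusted p = 0.465 by camera. Counts of type 2 cytokines and receptors were none higher without U1, U2 or T2, 3 higher without T3 and 1 lower without U1, U2, T1 or T2. Ccr4 (-1.62, adjusted p = 0.0079), a receptor on skin-homing T cells, fell, and Il1rl1 (1.21, adjusted p = 0.0196, 0.0659 without U1, 0.0587 without U2 and 0.067 without T2), the receptor of IL-33, rose. Gata3 (-0.43, adjusted p = 0.0338, 0.115 without U1, 0.0882 without U2, 0.0863 without T1 and 0.112 without T2) fell. Il4 had 6 and 16 reads and Il13 21 and 9 reads in the untreated and treated groups, with ratios of 2.29 (95% counting interval 0.85 to 7.14) and 0.368 (95% counting interval 0.148 to 0.838). Among IL-4 and IL-13 responsive genes, 3 of 15 tested members rose, namely Arg1, Chil3 and Alox15, and 4 fell, namely Retnla, Ccl22, Tgm2 and Mgl2 (4 higher and 6 lower adjusted over the list alone). IL-4 and IL-13 responsive genes did not pass as a list, with adjusted p = 0.787 by camera. Counts of IL-4 and IL-13 responsive genes were 1 higher without U1, U3, T1 or T2. By camera their direction was lower, while their median (0.15, or 0.28 without untreated replicate 3) and mean (0.061) were positive. Chil3 (2.98, adjusted p = 0.0089) rose, whereas Mgl2 (-1.45, adjusted p = 0.0055) and Retnla (-1.02, adjusted p = 0.0092), both marks of alternatively activated macrophages, fell. Ccl17 had 20 and 16 reads, a ratio of 0.686 (95% counting interval 0.333 to 1.39). Il1rl1 was not called without a trend in the spread (adjusted p over the alternatives 2.11e-04 to 0.067). Gata3 was not called with the trend with reads per base removed or without a trend in the spread (adjusted p over the alternatives 0.0049 to 0.115). Arg1 was not called with limma-voom or without a trend in the spread, U1, U3, T1 or T2 (adjusted p over the alternatives 0.0012 to 0.0921). Alox15 was not called with DESeq2 or the trend with reads per base removed, in the 4 libraries of like depth or without U1, U2, U3, T1, T2 or T3 (adjusted p over the alternatives 0.031 to 0.14). Ccl22 was not called without a trend in the spread or T2 (adjusted p over the alternatives 1.06e-05 to 0.0596). Tgm2 was not called with limma-voom or the trend with reads per base removed, in the 4 libraries of like depth or without a trend in the spread, U1, U2, T1 or T3 (adjusted p over the alternatives 0.0047 to 0.148).

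Of itch mediators and receptors, 2 of 14 tested members rose, namely Osm and Nppb, and 1 fell, namely Il31ra (2 higher and 1 lower adjusted over the list alone). Itch mediators and receptors did not pass as a list, with adjusted p = 0.857 by camera. Counts of itch mediators and receptors were 1 higher without U1, U3, T1 or T2 and 2 lower without U2. Il31ra (log2 fold change -2.09 ± 0.26 SE, adjusted p = 0.0028), the receptor of the itch cytokine IL-31, fell from 414 ± 29.5 to 102 ± 41.7 scaled reads, and Osm (3.38, adjusted p = 0.0117) rose. Nppb (1.22, adjusted p = 0.0376, 0.113 without U1, 0.0811 without U3, 0.118 without T1 and 0.108 without T2) rose as well. By camera the list's direction was lower, while its mean (0.24) was positive. Osm was not called with limma-voom (adjusted p over the alternatives 6.55e-07 to 0.0676). Nppb was not called with the trend with reads per base removed or without a trend in the spread (adjusted p over the alternatives 0.0086 to 0.118).

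Neutrophil markers had the highest median of the 34 tested lists, and 9 of 11 tested members rose (9 higher adjusted over the list alone). Neutrophil markers as a list had adjusted p = 5.05e-07 by camera and adjusted p = 0.362 with an estimated correlation. Retnlg (4.50, adjusted p = 0.0034) and Clec4d (3.49, adjusted p = 0.0039) rose, and Ly6g, below the filter, had no read in the untreated group and was at least 11.2-fold higher in the treated group. Means of the neutrophil list per library were 3.55 to 4.65 in untreated and 7.84, 7.36 and 6.19 in treated replicates 1, 2 and 3 on the log2 scale. For monocyte and macrophage markers, 8 of 20 tested members rose (14 higher adjusted over the list alone). Monocyte and macrophage markers as a list had adjusted p = 4.93e-07 by camera and adjusted p = 0.362 with an estimated correlation. Counts of monocyte and macrophage markers were 5 higher without U1, U2 or T2 and 13 higher without T3. Trem2 (2.47, adjusted p = 0.0011), a lipid receptor of macrophages, and Ly6c2 (2.41, adjusted p = 0.0064), a marker of inflammatory monocytes, rose, while Adgre1 (0.58, adjusted p = 0.0611, 0.039 without U3) did not pass. Adgre1 was called with DESeq2 (adjusted p over the alternatives 0.0283 to 0.187).

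Among T and NK lymphocyte markers, 10 of 17 tested members rose (11 higher and 2 lower adjusted over the list alone). T and NK lymphocyte markers as a list had adjusted p = 0.0066 by camera and adjusted p = 0.362 with an estimated correlation. Counts of T and NK lymphocyte markers were 6 higher without U1, U2 or T1 and 4 higher without T2. Icos (1.98, adjusted p = 0.0034), Cd28 (1.99, adjusted p = 0.0095) and Cd4 (2.39, adjusted p = 0.0114) rose. The list was not uniform, with 12 positive and 5 negative fold changes. Cd3e (-0.49, adjusted p = 0.102), a shared part of the T cell receptor complex, was among the negative ones and did not pass. For mast cell and basophil markers, 6 of 12 tested members rose (7 higher and 1 lower adjusted over the list alone). Mast cell and basophil markers as a list had adjusted p = 0.0043 by camera and adjusted p = 0.386 with an estimated correlation. Counts of mast cell and basophil markers were 3 higher without U1 or U2, 1 higher without T2 and 1 lower without T3. The list was not called in the 4 libraries of like depth (adjusted p 1.72e-04 to 0.0527 over the alternatives other than the estimated correlation). Hdc (2.27, adjusted p = 0.0064), which makes histamine, rose, as did Mcpt8 (3.26, adjusted p = 0.0184, 0.0612 without U1, 0.0564 without U2, 0.0505 without T1 and 0.075 without T2), a basophil protease. Among eosinophil markers, 1 of 3 tested members rose, namely Siglecf, and 1 fell, namely Ear2 (2 higher and 1 lower adjusted over the list alone). Eosinophil markers did not pass as a list, with adjusted p = 0.787 by camera. Counts of eosinophil markers were none higher without U1, U2, U3, T1, T2 or T3 and none lower without U1. The values were Siglecf (1.54, adjusted p = 0.0474, 0.0612 without U1, 0.0654 without U2, 0.0761 without U3, 0.104 without T1, 0.159 without T2 and 0.0527 without T3) and Ear2 (-1.56, adjusted p = 0.0138, 0.0581 without U1), and the Ear family shares reads. In the dendritic and Langerhans cell list, 2 of 18 tested members rose, namely Fscn1 and Cd80, and 4 fell, namely Cd207, Cd209a, H2-Ab1 and H2-Eb1 (2 higher and 5 lower adjusted over the list alone). Dendritic and Langerhans cell genes did not pass as a list, with adjusted p = 0.134 by camera, 0.0159 without U2 and 0.039 without T2. Counts of dendritic and Langerhans cell genes were 1 higher without U1, none higher without U2, T1 or T2, 1 lower without U1, U3, T1 or T2 and 2 lower without U2 or T3. The list was called in the 4 libraries of like depth (adjusted p 0.0159 to 0.628 over the alternatives other than the estimated correlation). Cd207 (log2 fold change -1.39 ± 0.20 SE, adjusted p = 0.0044), the Langerhans cell lectin, fell from 258 ± 34.3 to 99 ± 26.7 scaled reads. B and plasma cell markers had 2 tested members and no list test, with 0 members called by limma (1 at an unadjusted p under 0.05, 0 called by edgeR and 0 by DESeq2) and Cd79b (1.00, adjusted p = 0.121) as an example. Cd3e was called lower with the trend with reads per base removed or without a trend in the spread (adjusted p over the alternatives 0.0378 to 0.287). Siglecf was not called with DESeq2, RLE scaling, upper quartile scaling, edgeR, TMM scaling or the trend with reads per base removed or without a trend in the spread (adjusted p over the alternatives 0.026 to 0.159). Fscn1 was not called with limma-voom or RLE scaling or without a trend in the spread, U1, U2, T1 or T2 (adjusted p over the alternatives 0.0048 to 0.127). Cd80 was not called without U2, T1 or T2 (adjusted p over the alternatives 0.0089 to 0.0712). Cd209a was not called without a trend in the spread, U1, U3, T1 or T2 (adjusted p over the alternatives 0.0045 to 0.0984). H2-Ab1 was not called with the trend with reads per base removed or without a trend in the spread, U1, U2, U3, T1, T2 or T3 (adjusted p over the alternatives 0.0158 to 0.24). H2-Eb1 was not called with the trend with reads per base removed, in the 4 libraries of like depth or without a trend in the spread, U1, U2, U3, T1, T2 or T3 (adjusted p over the alternatives 0.0286 to 0.152).

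**Figure D2:**
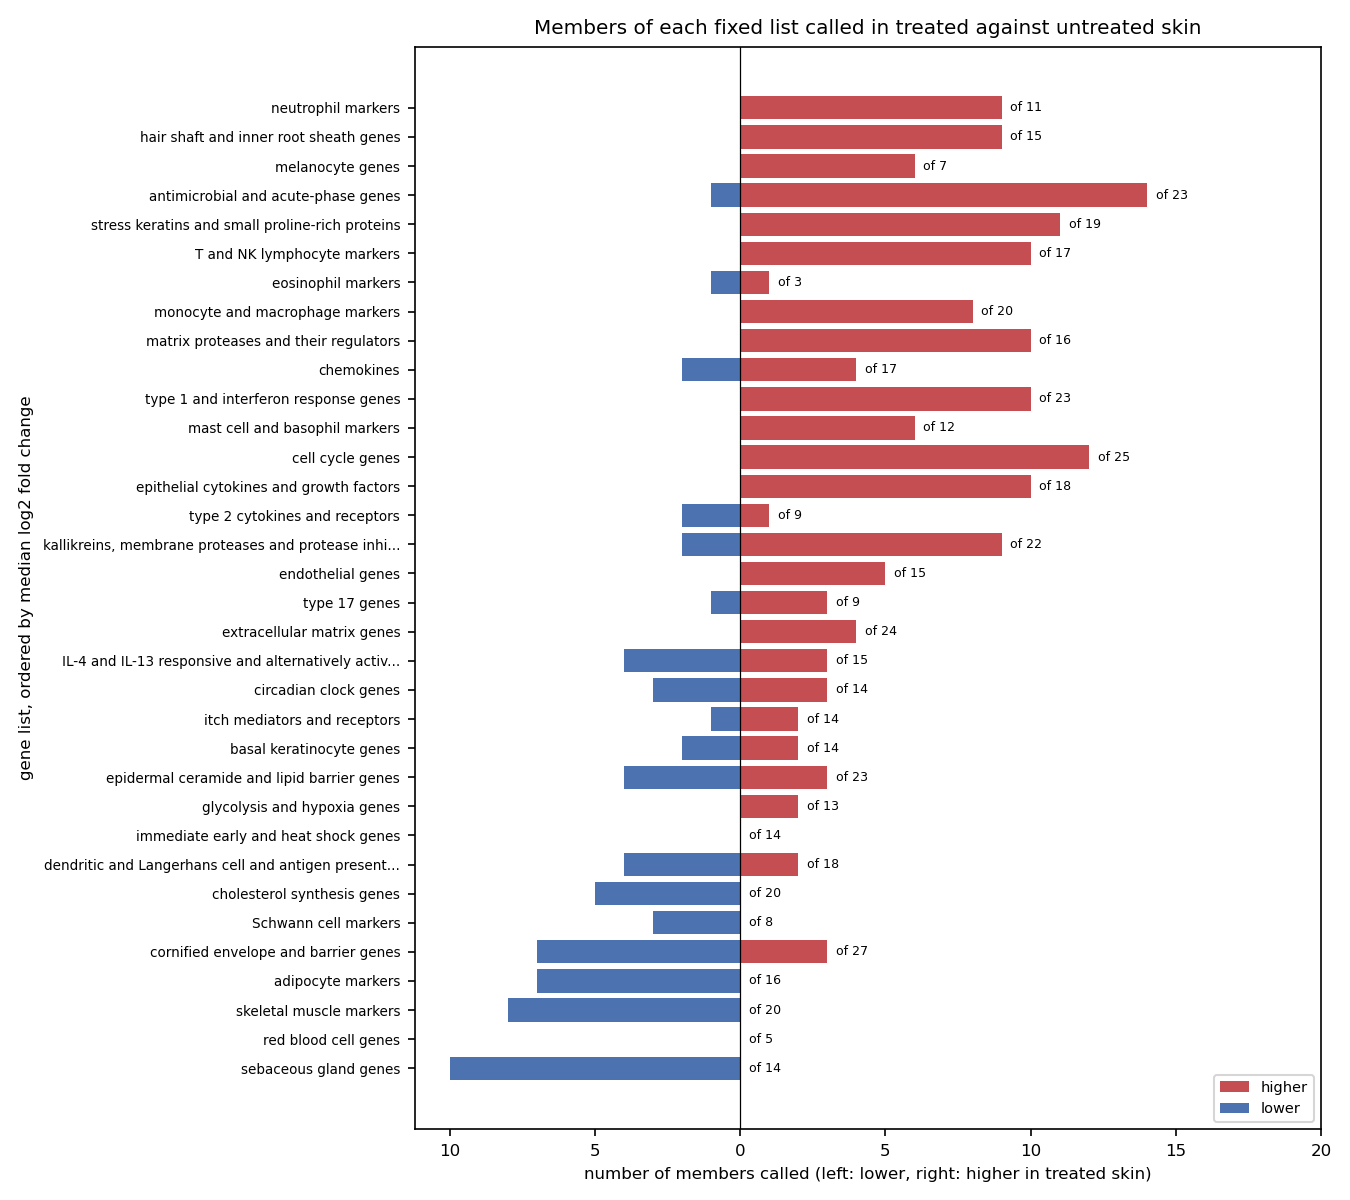
Number of members of each of the 34 tested lists called higher (red, right) or lower (blue, left) in treated skin, with lists ordered by median log2 fold change and the number of tested members beside each bar. Neutrophil markers stand at the top with 9 of 11 members higher, and sebaceous gland genes at the bottom with 10 of 14 lower.

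In the stress keratin and small proline-rich list, 11 of 19 tested members rose (12 higher adjusted over the list alone). Stress keratins and small proline-rich proteins as a list had adjusted p = 4.53e-06 by camera and adjusted p = 0.362 with an estimated correlation. Counts of stress keratins and small proline-rich proteins were 1 lower without T3. Sprr2b (log2 fold change 5.52 ± 0.37 SE, adjusted p = 3.91e-04), a precursor of the cornified envelope, rose from 5.2 ± 2.79 to 265 ± 47.4 scaled reads. Members of the Sprr2 family share reads, so their single values are uncertain, and Sprr2a1 and Sprr2a2 hold the same values. Of the wound keratins Krt6b (0.66, adjusted p = 0.0444, 0.0528 without U1, 0.14 without U2, 0.0989 without U3, 0.13 without T1 and 0.14 without T2) rose, while Krt6a (0.19, adjusted p = 0.5, 0.0115 without T3) and Krt16 (0.18, adjusted p = 0.43, 0.0169 without T3) did not pass over the 6 libraries. Krt6b was not called with limma-voom, RLE scaling, edgeR or TMM scaling or without a trend in the spread (adjusted p over the alternatives 0.0024 to 0.14). Krt6a was called in the 4 libraries of like depth (adjusted p over the alternatives 0.0072 to 0.899). Krt16 was called with the trend with reads per base removed or in the 4 libraries of like depth (adjusted p over the alternatives 0.0109 to 0.817).

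Of the cornified envelope and barrier genes, 3 of 27 tested members rose, namely Rptn, Casp14 and Tgm3, and 7 fell (3 higher and 12 lower adjusted over the list alone). Cornified envelope and barrier genes as a list had adjusted p = 0.001 by camera and adjusted p = 0.376 with an estimated correlation. Counts of cornified envelope and barrier genes were 3 lower without U1 or T2 and 4 lower without U2 or T1. The list was not called with the trend with reads per base removed or without genes over 0.2 reads per base (adjusted p 8.07e-05 to 0.942 over the alternatives other than the estimated correlation). Krt77 (log2 fold change -2.44 ± 0.37 SE, adjusted p = 0.0053) fell from 2661 ± 176 to 557 ± 313 scaled reads, and Lor (-0.54, adjusted p = 0.0113), the loricrin gene of the cornified envelope, fell, whereas Rptn (0.98, adjusted p = 8.22e-04) and Tgm3 (1.85, adjusted p = 8.22e-04), which crosslinks envelope proteins, rose. Krt10 (-0.21, adjusted p = 0.167) did not pass, and Flg was not analysed here. The direction of the cornified envelope list turned without genes over 0.2 reads per base (adjusted p = 0.942). Lor was not called with the trend with reads per base removed (adjusted p over the alternatives 2.80e-05 to 0.131).

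For kallikreins, membrane proteases and protease inhibitors, 9 of 22 tested members rose and 2 fell, namely Klk5 and Cst6 (11 higher and 4 lower adjusted over the list alone). Kallikrein and protease inhibitor genes as a list had adjusted p = 0.018 by camera (0.0659 without T1) and adjusted p = 0.386 with an estimated correlation. Counts of kallikrein and protease inhibitor genes were none lower without U1, U3 or T2, 1 lower without U2 and 4 lower without T3. The list was not called with the rank-based test or without genes over 0.2 reads per base (adjusted p 3.87e-05 to 0.462 over the alternatives other than the estimated correlation). Klk14 (2.61, adjusted p = 0.0013) and Klk13 (1.78, adjusted p = 0.0021), proteases that loosen the stratum corneum, and Serpinb3a (3.76, adjusted p = 0.0011), an inhibitor with close paralogs, rose. Of the basal keratinocyte genes, 2 of 14 tested members rose, namely Lama3 and Cdh3, and 2 fell, namely Krt15 and Col17a1 (3 higher and 3 lower adjusted over the list alone). Basal keratinocyte genes did not pass as a list, with adjusted p = 0.787 by camera. Counts of basal keratinocyte genes were 1 higher without T1 or T2, 4 higher without T3 and 1 lower without U1. Cdh3 (0.50, adjusted p = 0.0075) rose and Krt15 (-0.45, adjusted p = 0.0086) fell. Among epidermal ceramide and lipid barrier genes, 3 of 23 tested members rose, namely Sptlc2, Ugcg and Degs2, and 4 fell, namely Elovl1, Elovl4, Elovl6 and Cers4 (3 higher and 7 lower adjusted over the list alone). Epidermal ceramide and lipid barrier genes did not pass as a list, with adjusted p = 0.195 by camera. Counts of epidermal ceramide and lipid barrier genes were 1 lower without U1, 2 lower without T2 and 7 lower without T3. Degs2 (1.20, adjusted p = 0.0025), which makes phytoceramides, rose and Cers4 (-0.49, adjusted p = 0.0131) fell. Klk5 was not called with limma-voom, no filter on low reads, reads estimated from filled positions or the trend with reads per base removed, in the 4 libraries of like depth or without a trend in the spread, U1, U2, U3, T1 or T2 (adjusted p over the alternatives 0.0317 to 0.327). Cst6 was not called without U1, U3 or T2 (adjusted p over the alternatives 0.006 to 0.0606). Lama3 was not called without a trend in the spread, T1 or T2 (adjusted p over the alternatives 6.64e-05 to 0.0557). Col17a1 was not called with the trend with reads per base removed or without U1 (adjusted p over the alternatives 1.33e-04 to 0.106). Ugcg was not called with DESeq2 or RLE scaling or without a trend in the spread, U1, U2, U3, T1 or T2 (adjusted p over the alternatives 0.0128 to 0.0912). Elovl1 was not called without a trend in the spread, U1, U2 or T2 (adjusted p over the alternatives 0.0032 to 0.074). Elovl4 was not called with the trend with reads per base removed or without a trend in the spread, U1, U3 or T2 (adjusted p over the alternatives 7.21e-04 to 0.403). Elovl6 was not called with the trend with reads per base removed or without a trend in the spread or U1 (adjusted p over the alternatives 1.50e-04 to 0.143). Cers4 was not called with the trend with reads per base removed (adjusted p over the alternatives 1.06e-04 to 0.0678).

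Among cell cycle genes, 12 of 25 tested members rose (20 higher adjusted over the list alone). Cell cycle genes as a list had adjusted p = 1.68e-07 by camera and adjusted p = 0.362 with an estimated correlation. Counts of cell cycle genes were 7 higher without U1, 6 higher without U2 and 5 higher without T1 or T2. Cenpf (0.67, adjusted p = 0.0044), Bub1 (1.04, adjusted p = 0.0074) and Top2a (0.53, adjusted p = 0.0111) rose, and Mki67 (0.57, adjusted p = 0.0226, 0.0755 without T1 and 0.0652 without T2) went from 1640.5 ± 295 to 2407 ± 221 scaled reads. Among matrix proteases and their regulators, 10 of 16 tested members rose (13 higher adjusted over the list alone). Matrix proteases and their regulators as a list had adjusted p = 2.68e-07 by camera and adjusted p = 0.362 with an estimated correlation. Counts of matrix proteases and their regulators were 6 higher without T2. Mmp13 (log2 fold change 4.16 ± 0.56 SE, adjusted p = 0.0038) rose from 19.6 ± 11.9 to 348 ± 170.0 scaled reads, and Mmp11 (1.43, adjusted p = 8.76e-04) rose too. In the extracellular matrix list, 4 of 24 tested members rose, among them Col5a1, Col5a2 and Lox (4 higher adjusted over the list alone). Extracellular matrix genes as a list had adjusted p = 0.0242 by camera (0.0605 without U2 and 0.276 without T2) and adjusted p = 0.596 with an estimated correlation. Counts of extracellular matrix genes were 2 higher without U1, U2 or T2 and 1 lower without T1. The list was not called without genes over 0.2 reads per base or a trend in the spread (adjusted p 6.73e-04 to 0.276 over the alternatives other than the estimated correlation). Lox (0.84, adjusted p = 0.0072), a collagen crosslinker, and Col5a2 (0.43, adjusted p = 0.0297, 0.0833 without U1, 0.0865 without U2 and 0.105 without T2), a fibrillar collagen gene, rose. For endothelial genes, 5 of 15 tested members rose, namely Vwf, Emcn, Selp, Icam1 and Vcam1 (7 higher adjusted over the list alone). Endothelial genes as a list had adjusted p = 0.005 by camera and adjusted p = 0.369 with an estimated correlation. Counts of endothelial genes were 3 higher without U2 and 2 higher without U3, T1 or T2. Vcam1 (1.49, adjusted p = 0.007), an adhesion molecule for leukocytes, rose. Glycolysis and hypoxia genes were not called as a list (adjusted p = 0.652 by camera), and 2 of 13 tested members rose, namely Slc2a1 and Adm (2 higher adjusted over the list alone). Counts of glycolysis and hypoxia genes were none higher without U1, U3, T1 or T2 and 1 higher without U2. Slc2a1 (0.61, adjusted p = 0.032, 0.0858 without U1, 0.0907 without U2, 0.0674 without U3, 0.0863 without T1 and 0.107 without T2), a glucose transporter, rose, and the list's median (-0.066) and mean (0.058) differed in sign. Mki67, Col5a2 and Slc2a1 were not called without a trend in the spread (adjusted p over the alternatives 0.0013 to 0.0755, 0.0087 to 0.105 and 7.06e-04 to 0.107). Col5a1 was not called in the 4 libraries of like depth or without a trend in the spread, U1, U2 or T2 (adjusted p over the alternatives 0.0033 to 0.111). Emcn was not called with DESeq2, RLE scaling, upper quartile scaling, edgeR or TMM scaling or without a trend in the spread, U1, U3, T1, T2 or T3 (adjusted p over the alternatives 0.0273 to 0.144). Selp was not called with DESeq2 or the trend with reads per base removed or without a trend in the spread, U2, U3, T1 or T2 (adjusted p over the alternatives 0.0181 to 0.0968). Icam1 was not called with DESeq2, limma-voom, RLE scaling, upper quartile scaling, edgeR or TMM scaling, in the 4 libraries of like depth or without a trend in the spread, U1, U2, U3, T1 or T2 (adjusted p over the alternatives 0.0358 to 0.185). Adm was not called with limma-voom or the trend with reads per base removed or without a trend in the spread, U1, U2, U3, T1 or T2 (adjusted p over the alternatives 0.0049 to 0.122).

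Of the sebaceous gland genes, 10 of 14 tested members fell (13 lower adjusted over the list alone). Sebaceous gland genes as a list had adjusted p = 1.68e-07 by camera and adjusted p = 0.362 with an estimated correlation. Counts of sebaceous gland genes were 4 lower without U1, 6 lower without U3 and 5 lower without T1 or T2. Dgat2 (-0.57, adjusted p = 0.0051) and Soat1 (-0.43, adjusted p = 0.0111), which make storage lipids, fell. Of the adipocyte markers, 7 of 16 tested members fell (13 lower adjusted over the list alone). Adipocyte markers as a list had adjusted p = 4.00e-08 by camera and adjusted p = 0.362 with an estimated correlation. Lep (log2 fold change -1.89 ± 0.21 SE, adjusted p = 0.0016), the gene of leptin, fell from 695 ± 122 to 189 ± 51.1 scaled reads, and Fasn (-0.93, adjusted p = 0.0044), the fatty acid synthase gene, fell. Of the skeletal muscle markers, 8 of 20 tested members fell (19 lower adjusted over the list alone). Skeletal muscle markers as a list had adjusted p = 3.06e-08 by camera and adjusted p = 0.362 with an estimated correlation. Counts of skeletal muscle markers were 3 lower without U1, 2 lower without U2 and 1 lower without T1 or T2. Myh2 (-0.54, adjusted p = 0.0224, 0.0678 without U1, 0.0627 without U2 and 0.059 without T1) and Mb (-0.53, adjusted p = 0.0239, 0.0684 without U2 and 0.0722 without T2) fell. In cholesterol synthesis, 5 of 20 tested members fell, among them Lss, Nsdhl, Dhcr7 and Insig1 (8 lower adjusted over the list alone). Cholesterol synthesis genes as a list had adjusted p = 6.44e-05 by camera and adjusted p = 0.362 with an estimated correlation. Counts of cholesterol synthesis genes were 1 lower without U1, U3 or T2, 3 lower without U2 or T1 and 2 lower without T3. Insig1 (-0.78, adjusted p = 0.0013) and Dhcr7 (-0.33, adjusted p = 0.0273, 0.103 without U1, 0.0659 without U3, 0.0669 without T1 and 0.105 without T2) fell. For Schwann cell markers, 3 of 8 tested members fell, among them Prx (4 lower adjusted over the list alone). Schwann cell markers as a list had adjusted p = 0.0234 by camera (0.103 without T1) and adjusted p = 0.362 with an estimated correlation. Prx (-0.80, adjusted p = 0.0143) fell. In the 4 libraries of like depth the medians were -0.18 for muscle, -0.23 for adipocyte and -0.54 for sebaceous gland genes, against -0.36, -0.35 and -0.55 in all 6, and -0.18, -0.24 and -0.45 with the trend with reads per base removed. Myh2 and Mb were not called without a trend in the spread (adjusted p over the alternatives 2.20e-04 to 0.0698 and 0.0015 to 0.0722). Lss was not called with limma-voom, no filter on low reads or reads estimated from filled positions or without genes over 0.2 reads per base, a trend in the spread, U1, U3, T1, T2 or T3 (adjusted p over the alternatives 0.0172 to 0.155). Nsdhl was not called in the 4 libraries of like depth or without a trend in the spread, U1, U2, U3, T2 or T3 (adjusted p over the alternatives 0.0227 to 0.132). Dhcr7 was not called with the trend with reads per base removed or without a trend in the spread (adjusted p over the alternatives 0.0107 to 0.105).

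Red blood cell genes were lower as a list, with adjusted p = 0.0234 by camera (0.0519 without U3 and 0.0824 without T2) and adjusted p = 0.39 with an estimated correlation. The list was not called with edgeR (adjusted p 0.0071 to 0.0824 over the alternatives other than the estimated correlation). By member, 0 of 5 were called by limma, 3 at an unadjusted p under 0.05, 0 called lower by edgeR and 0 by DESeq2. Counts of red blood cell genes were 1 lower without T3. The globin genes share reads. Median fold changes of all tested genes fell with reads per base, as the plot of fold change by reads per base shows. Recovered reads never exceeded 0.923 per base of transcript.

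**Figure D3:**
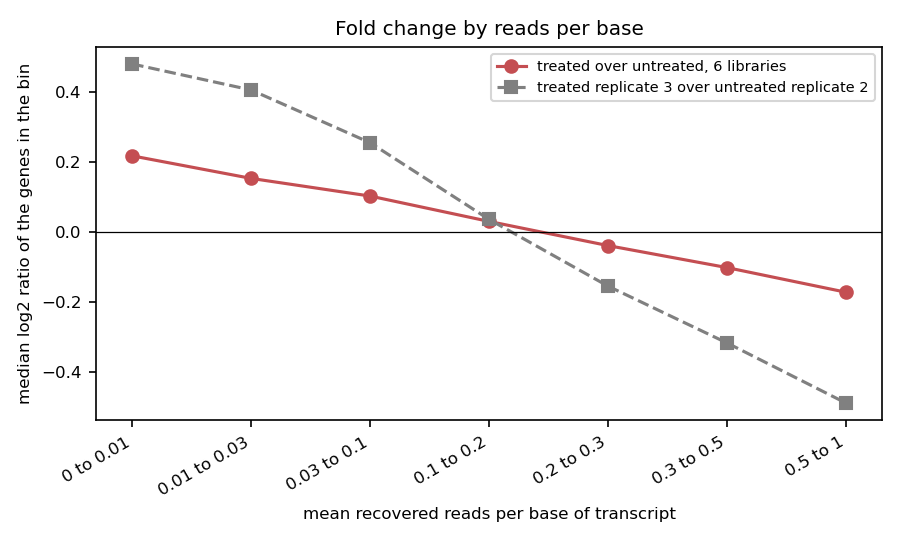
Median log2 ratio of all tested genes, binned by recovered reads per base of transcript, for treated over untreated skin (red, 6 libraries) and for treated replicate 3 over untreated replicate 2 (grey). The median runs from 0.22 in the lowest bin to -0.17 in the highest, and from 0.48 to -0.49 for the deepest against the shallowest library.

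In the hair shaft and inner root sheath list, 9 of 15 tested members rose (12 higher adjusted over the list alone). Of its 33 fixed members 24 had a row. The hair shaft keratin genes Krt31, Krt33a, Krt36, Krt81, Krt83, Krt85 and Krt86 were below the filter. The called members were mostly inner root sheath genes, with Krt35 the hair shaft keratin gene among them. Hair shaft and inner root sheath genes as a list had adjusted p = 1.68e-07 by camera and adjusted p = 0.362 with an estimated correlation. Krt71 went from 13.3 ± 2.04 to 423 ± 355 scaled reads (4.48 ± 0.58 SE, adjusted p = 0.0032), and Shh (3.85, adjusted p = 0.0016), a signal of the growing follicle, rose. Of the melanocyte genes, 6 of 7 tested members rose (6 higher adjusted over the list alone). Melanocyte genes as a list had adjusted p = 7.63e-07 by camera and adjusted p = 0.362 with an estimated correlation. Tyr (log2 fold change 2.95 ± 0.24 SE, adjusted p = 8.22e-04), the enzyme that starts melanin synthesis, rose from 24.8 ± 7.06 to 196 ± 35.9 scaled reads. Treated libraries differed in the hair list, with means of 7.64, 6.47 and 8.55 in treated replicates 1, 2 and 3 against 4.69 to 4.84 in untreated libraries. In neutrophil markers the highest of the treated means was in treated replicate 1 and the lowest in treated replicate 3. Krt71 was not called with limma-voom (adjusted p over the alternatives 6.82e-08 to 0.0702).

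**Figure D4:**
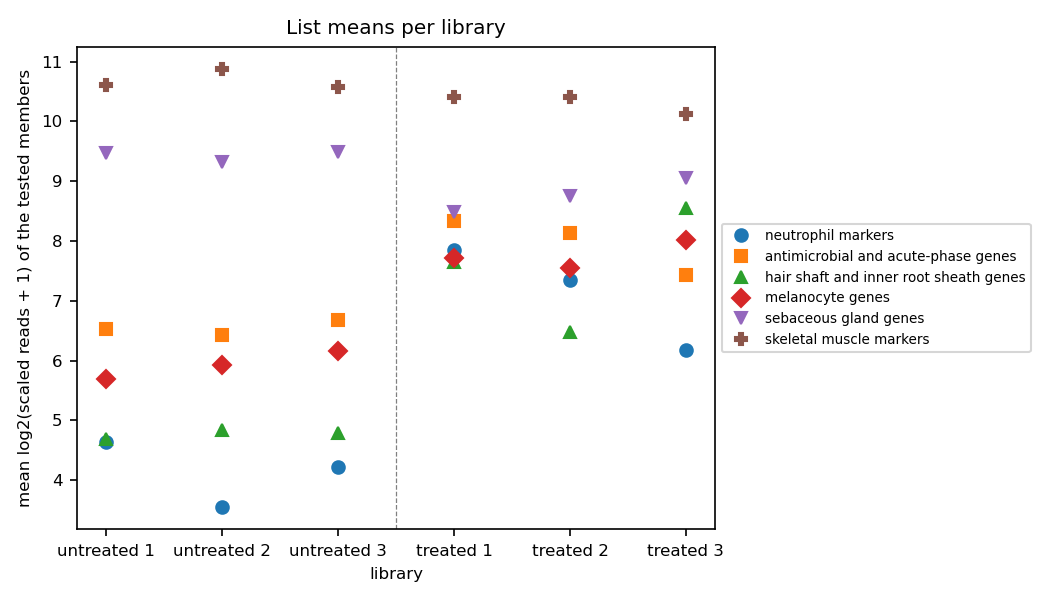
Mean log2(scaled reads + 1) of the tested members of 6 lists in each of the 6 libraries, untreated left and treated right of the dashed line. Hair genes run from 6.47 in treated replicate 2 to 8.55 in treated replicate 3, and neutrophil markers from 6.19 to 7.84 in the treated libraries.

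Of the circadian clock genes, 3 of 14 tested members rose, namely Per1, Per3 and Dbp, and 3 fell, namely Nr1d1, Arntl and Npas2 (3 higher and 4 lower adjusted over the list alone). Circadian clock genes did not pass as a list, with adjusted p = 0.965 by camera. Counts of circadian clock genes were none higher without U1 or T2, 1 higher without U2 and 1 lower without U1 or U2. Npas2 (-1.24, adjusted p = 0.0046) and Arntl (-0.68, adjusted p = 0.0159, 0.0536 without U1 and 0.0543 without U2) fell, and Dbp (0.55, adjusted p = 0.0159, 0.0637 without U1 and 0.0708 without T2) and Per3 (0.61, adjusted p = 0.0184, 0.069 without U1, 0.0574 without U2 and 0.0716 without T2) rose. By camera the list's direction was lower, while its median (0.084) and mean (0.046) were positive. Immediate early and heat shock genes did not pass as a list (adjusted p = 0.0524 by camera, 0.0375 without U1, 0.0311 without U2 and 0.0457 without T3). The list was called with RLE scaling, at least 1 CPM in 3 libraries, the rank-based test or TMM scaling or in the 4 libraries of like depth (adjusted p 0.0225 to 0.522 over the alternatives other than the estimated correlation). By member, 0 of 14 were called by limma, 1 at an unadjusted p under 0.05, 1 called lower by edgeR and 0 by DESeq2. Mitochondrially encoded genes were not analysed here. Of the sex-linked genes Xist was measured, at 5324 to 6464 scaled reads over the 6 libraries. Per1 was not called with edgeR, TMM scaling or the trend with reads per base removed, in the 4 libraries of like depth or without a trend in the spread, U1, U2, T1, T2 or T3 (adjusted p over the alternatives 0.0031 to 0.138). Per3 was not called in the 4 libraries of like depth or without a trend in the spread (adjusted p over the alternatives 0.0022 to 0.0716). Nr1d1 was not called in the 4 libraries of like depth or without a trend in the spread, U1, U2, U3, T1, T2 or T3 (adjusted p over the alternatives 0.0221 to 0.101). Arntl was not called without a trend in the spread (adjusted p over the alternatives 2.54e-04 to 0.0543).

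Over the 34 lists tested, 16 were higher and 7 lower at the preset correlation. With an estimated correlation camera called 0 of them, 1 had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 12. At the preset correlation, other splits of the 6 samples into 3 and 3 called up to 14 lists in 1 direction. Those splits mix treated and untreated libraries unequally, so part of the treatment difference remains in them.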

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

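The edgeR, TMM, pseudocount, filled-position, trend-removal, like-depth, 0.2 reads per base and untrended settings were chosen after seeing the data. Counts of genes stayed within 1.5 times of 1439 higher and 1123 lower under DESeq2, limma-voom, RLE, upper quartile, both filters, removal of hair and muscle genes or of genes over 0.2 reads per base, the authors' deposited comparison, edgeR, TMM, both pseudocounts, filled positions, trend removal and the 4 libraries of like depth. Adjusted p under 0.01 gave 362 and 288, a test against a 1.5-fold change 137 and 57, both by their stricter construction, and limma without a trend in the spread 922 and 640, for which the cause was not tested. Leaving out 1 library gave 597 to 1389 higher and 518 to 1333 lower genes, with fewer samples in each fit. No gene called by limma over the 6 libraries was called in the opposite direction under any alternative. Which direction had more genes depended on the setting. Lower genes outnumbered higher ones with DESeq2 (1247 higher, 1336 lower), RLE scaling (1237, 1311) and TMM scaling (1271, 1278). The same held with trend removal (1226, 1260), the 4 libraries of like depth (1330, 1375) and the authors' deposited comparison (1275, 1328). All other settings gave more higher than lower genes. Library-size scaling is the main scaling and gives no separate value.

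The replicate block gave 1348 higher and 1096 lower genes, of which 2206 were called in the same direction without it, and 16 higher and 8 lower lists. With the block 9 of the called genes named in the text were not called, namely Alox15, Emcn, Fscn1, H2-Ab1, H2-Eb1, Icam1, Klk5, Lss and Nsdhl. Samples of the same number had correlations of deviations of -0.085, -0.054 and 0.054, which give no sign that the numbers pair the samples.

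With an estimated correlation camera called 0 lists higher and 0 lower (1 at an unadjusted p under 0.05), and 12 passed by fry. Without genes over 0.2 reads per base 4 lists were lower, adipocyte and muscle lists had too few genes left for a test, and the cornified envelope list turned in direction with adjusted p = 0.942; fewer genes were tested. Of 131 called genes named in the text, 82 kept the call whichever library was left out and 78 under the other alternatives that give them a value. Of 23 called lists, 18 kept the call whichever library was left out and 17 under the other alternatives that could test them, the estimated correlation aside. The lists that lost it there were chemokines, cornified envelope, kallikreins and protease inhibitors, extracellular matrix, mast cells and basophils, and red blood cells. The cause was not tested. Depth limits the low cytokine genes, where ratios rest on few reads.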

Other observations

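The tests of compression, of unequal depth, of the trend with reads per base, of collection day and of tissue shares were chosen after the results they measure had been seen, and the 4 libraries of like depth were chosen with the list means of each library in view.

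The first pattern is the rise of hair shaft, inner root sheath and melanocyte genes. Compression of abundant genes is argued against by the trend of all genes with reads per base, whose bin medians ran from 0.22 to -0.17, while the hair and melanocyte medians were 2.15 and 1.88 in the 4 libraries of like depth. With reads estimated from filled positions the smaller median was 2.22. That estimate left the trend of all genes largely in place, so it decides nothing on its own. A larger share of whole hair follicles in an unchanged state is argued against by 14 resting follicle and outer root sheath genes. They were fixed before their values were seen. Their median log2 fold change was -0.041, and the standard error of their mean over the genes was 0.13. Among them 3 were called lower and 0 higher by limma. Fgf18, a signal of resting follicles, had a log2 fold change of -1.71 (adjusted p = 0.0046). Foxc1 was at -0.72 (adjusted p = 0.0286) and Cd34 at -0.27 (adjusted p = 0.0433). Falls of single genes do not settle the share. A larger share together with entry into growth stays open, since a fall of resting genes could offset it. Collection of untreated skin at another time after depilation cannot be told apart from the treatment, because 0 untreated samples carry a collection day. Follicles entering growth in treated skin, or at another time after depilation, may both account for the rise as a hypothesis.

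The second pattern is the fall of skeletal muscle, adipocyte and sebaceous gland genes. Reads estimated from filled positions gave -0.49 for the median nearest 0, but that estimate left the trend of all genes largely in place (-0.17 before and -0.16 after in the highest bin), so it leaves the explanation open although the value lies past the bound set for it. In the 4 libraries of like depth the medians were -0.18 for muscle, -0.23 for adipocyte and -0.54 for sebaceous genes, with standard errors over the members of 0.025, 0.13 and 0.25. The sebaceous median lay past its bound by more than that error, which argues against unequal depth as the whole cause there. Members vary together between libraries (estimated correlation 0.35 for sebaceous genes), so errors over members understate the spread. The fat median lay past the bound set for it but not by its standard error, a condition added after its value was known. Once the trend of each library with reads per base was removed, the list means of the groups still differed by -0.21 for muscle, -0.41 for adipocyte and -0.62 for sebaceous genes, with standard errors over the libraries of 0.045, 0.12 and 0.21, which argues against that trend as the whole cause and leaves unequal depth open as a part of the fall of muscle and fat genes. With reads estimated from filled positions, the SD of the fold changes over the muscle genes was 0.84 times their median standard error. Muscle genes varied together between libraries (estimated correlation 0.86), which lowers that ratio whatever the cause, so a lower share of muscle stays open. For adipocyte genes the ratio was 3.75, past the bound set for it, so their fold changes differed by more than their errors. A lower share of fat would give equal fold changes only if no other cells expressed these genes, which was not tested. A lower share of fat therefore stays open too. A response of sebaceous and fat cells to the treatment stays open as a hypothesis.

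The third pattern is that some clock genes of opposite phase moved apart, with Npas2 and Arntl lower and Dbp, Per1 and Per3 higher, although Nr1d1, which shares the phase of Dbp, was lower. Another time of day at collection predicts that clock output genes follow, and 2 of 4 did so at an unadjusted p under 0.05 (Wee1, log2 fold change 0.48, and Bhlhe40, 0.28), while Usp2 (-0.29) went the other way and Nfil3 was at -0.043. This cannot be told apart from an effect of the treatment on the clock, since no label gives the hour of collection.

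With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1439 higher and 1123 lower genes and the highest count of the other splits was 0 by limma, with up to 840 genes at an unadjusted p under 0.05. Every other split mixed treated and untreated libraries in both groups, which put the treatment difference into the spread within groups. Such mixing favours low gene counts, so the count of 0 does not argue against chance. For the lists the real split gave 16 higher and 7 lower. Another split gave up to 14 in one direction, higher on the side of U1, T1 and T2. Counting the larger direction of each other split, 5 splits, the real one included, gave as many as the lower lists. The other splits keep part of the treatment difference, so they do not measure what chance gives for the lists.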
